A study of Homo sapiens with 4 samples.

How the data were processed

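Total RNA of 4 cultures was measured on one-colour (Cy3) Agilent 4x44K arrays, 1 array per culture. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1, which subtracted background and gave each spot a processed signal, an intensity on a linear scale that the authors deposited without normalization between arrays. The authors also deposited a value table on the log2 scale, with a value per probe and array. Its normalization and centring are not given in the sources used here. The headers name the build hg19, and no coordinates are printed.

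The table was set against the scanner files. Differences between arrays in the table equalled differences of the mean log2 signal over spots without outlier flag, up to a constant per array. For the 999 probes printed at 10 spots, the residual SD of the bicalutamide difference was 5.11e-07 in T47D and 5.31e-07 in A3. In A3, averaging the linear signals of the same spots left an SD of 0.0298, and averaging log2 over all spots 0.0627. The table is therefore the same measurement with other array constants and no independent evidence. Its column medians were 0.0015 and 0.043 in T47D (DHT, then DHT and bicalutamide) and -0.12 and 0.012 in A3. The scale is log2, but what each probe was centred on stays unknown.

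In the main setting, log2 of the processed signal minus the array's 75th percentile over non-control spots was used. Spots with outlier flags were left out, and no spot was saturated. Spots of a probe were averaged, and a gene took the value of its probe with the highest mean log2 signal. Of 34127 non-control probes, 25422 were named through their RefSeq accession without version in a RefSeq gene table (assembly GRCh38.p14, used for names only), which gave 19483 genes. The other 8705 probes were not named and entered no comparison of genes. A gene was compared where its probe was well above background on both arrays. A gene above background on one array, with all its probes dim on the other, has an at-least fold: the bright value against the higher of the dim array's lowest signal among probes well above background and the dim probe's own signal.

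Samples were grouped by line and treatment. The comparisons were bicalutamide with DHT minus DHT alone in each line, A3 minus T47D under each treatment, the overlap of each pair, and the difference of the bicalutamide differences. Genes at least 2-fold apart were counted, without a test or p-value. As an alternative for bicalutamide in both lines, slide was fitted as a block with treatment in limma (lmFit and eBayes, Benjamini-Hochberg adjustment) over the genes measured on all 4 arrays, which leaves 1 residual degree of freedom and takes a difference between the lines as error. For 22 gene lists, the median difference was ranked among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. The lists, the threshold, the comparisons and the rule for named genes were fixed before the data were examined. In each direction, the rule took the 10 genes with the largest difference with bicalutamide in both lines and the 12 between the lines under both treatments, ranked by the smaller value. It also took the 8 largest per line, the 6 largest in the difference of differences, the 5 largest at-least folds per comparison, ESR1, PGR, CYP19A1, the androgen receptor targets, and up to 4 members of each other list. Some genes of the rule are not reported here, placeholder names were left out, and a gene outside the rule is said to be so where it is named.

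The alternatives set beforehand were quantile normalization, median scaling, normexp background correction with an offset of 50, other filters on dim genes, the mean over a gene's probes, the authors' value table and a 3-fold threshold. Normexp used the median spot and background signals in place of the mean signal, which the files do not hold. Removal of the brightness trend (lowess, span 0.3) was chosen after seeing the data. A log2 value was taken to have moved when it changed by more than the median SD over spots. Median scaling and the authors' value table differ from the main setting by a constant per array. A list's place among random lists therefore could not change under them. For the difference of differences, the filter for genes well above background on all 4 arrays keeps the genes of the main setting and changes nothing.

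The counting and ranking steps were tested on simulated data made from the measured signals with the between-probe spread. The simulated spread was the same at every brightness, with no brightness trend and no spread between cultures. The rates below therefore need not hold for the measured arrays. For the bicalutamide comparison in T47D (13453 genes), 50 of 50 genes with a true 3-fold change and 29 of 50 with a true 2-fold change passed 2-fold, and 0 of 13253 unchanged genes did. In A3 (15511 genes) these were 50 of 50, 21 of 50 and 3 of 15311. For A3 against T47D with DHT (14063 genes) they were 46 of 50, 24 of 50 and 191 of 13863. Of 200 lists of unchanged genes, 7 fell outside the central 95% in the simulation of bicalutamide in T47D, 11 in that of bicalutamide in A3, 15 in that of the lines with DHT and 11 in that of the lines with bicalutamide. These lists were drawn at random with noise independent between genes, so lists whose members vary together were not tested. For the fit with slide as a block (13376 genes), 50 of 50 genes with a true 2-fold change, 31 of 50 with a true 1.5-fold change and 5 of 13176 unchanged genes had an adjusted p under 0.05 in limma, on simulated arrays that varied by the between-probe spread. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp and the fit with slide as a block.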

Results

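Gene expression was measured on 4 one-colour oligonucleotide arrays in 2 human breast cancer cell lines. T47D is an established luminal line that expresses estrogen and progesterone receptors, and A3 is a line that the series title describes as resistant to aromatase inhibitors, drugs that block the conversion of androgens to estrogens. The labels do not state the parent line of A3, so a difference between the lines cannot be assigned to resistance. Each line was treated for 24 h with 1 nM dihydrotestosterone (DHT), an androgen that cannot be converted to estrogen, or with 1 nM DHT and 10 µM bicalutamide, an androgen receptor antagonist. Each of the 4 groups had 1 array, so there were no replicates within groups, no difference between single arrays could be tested, and every difference below describes these arrays. Of 43118 non-control spots, 29240 were well above background with DHT and 27500 with DHT and bicalutamide in T47D, against 33302 and 33676 in A3. The 2 T47D arrays lay on one slide and the 2 A3 arrays on another, so line and slide cannot be told apart. On both slides the DHT array was at position 3 and the bicalutamide array at position 4, so position cannot be told apart from treatment either. The number of arrays limits the precision. Within arrays, the log2 difference between the DHT and bicalutamide arrays had a median SD over repeated spots of 0.046 in T47D and 0.065 in A3, and a pooled SD between probes of one gene of 0.17 and 0.27. The spread between cultures was not measured.

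The first comparison addressed which transcripts differed in T47D when bicalutamide was added to DHT. No culture without DHT was measured, so whether a difference reverses an effect of DHT cannot be seen in either line. The genes that stood lowest with bicalutamide included members of the UGT2B family of glucuronidating enzymes: UGT2B11 was 10.4-fold lower, UGT2B7 6.27-fold lower and UGT2B10 5.29-fold lower. These paralogs are similar enough for their probes to cross-hybridise, so their separate values are uncertain. SEC14L2, a lipid-binding protein, was 5.71-fold lower, the dopamine receptor gene DRD2 4.76-fold lower, and SGK1, a steroid-responsive kinase, 4.67-fold lower. RANBP3L was 5.73-fold lower and RBP5, a retinol-binding protein, 4.43-fold lower. Among the genes that were higher, CACNG7 was 8.01-fold higher, PPP1R3C, a regulator of glycogen synthesis, 6.25-fold higher, and GBP2, an interferon-inducible GTPase, 5.25-fold higher. These genes were dim with DHT, at signals of 25.9, 24.8 and 29.1, so their fold sizes are uncertain.

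DNA replication genes were lower together in T47D with bicalutamide. All 29 measured members had a negative difference, with a median log2 difference of -0.46, below 10000 random lists of the same size and brightness, although none reached 2-fold. TYMS, which makes thymidylate, had a log2 difference of -0.66 and the origin-recognition gene ORC1 -0.60. Mitotic genes had a median of -0.47, also below those lists, with 25 of 26 members negative. The kinetochore gene NDC80 had a log2 difference of -0.80, the spindle checkpoint kinase TTK -0.71 and the cyclin-dependent kinase CDK1 -0.63. The measured androgen receptor targets did not shift as a list: their median was 0.025, inside the central 95% of random lists (-0.062 to 0.15), and just below 0 after median scaling. KLK3 and KLK4 did not enter this median. They were well above background with DHT (signals of 38.6 and 34.7) and not with bicalutamide (6.31 and 21.4). The list lay inside the range in each of the 9 other settings, among them that with no detection filter. Median scaling and the authors' value table could not have changed its rank. Of 24 measured members, 3 were at least 2-fold lower, namely SGK1, AZGP1 (2.25-fold lower) and NDRG1 (2.23-fold lower), and none was 2-fold higher. FKBP5, a chaperone gene induced by several steroid receptors, had a log2 difference of -0.73. Estrogen receptor targets had a median of 0.19, above the central 95% of random lists (-0.057 to 0.13), with the chemokine CXCL12 2.20-fold higher. Its other measured probes had log2 differences of 0.58 and 0.87, and the gene was under 2-fold with the mean over probes. Interferon response genes had a median of -0.15 against a range of -0.067 to 0.14, with IFI44 2.20-fold lower, and under 2-fold after normexp background correction. Of 19 steroid hormone metabolism genes 4 were at least 2-fold lower, namely UGT2B7, UGT2B10, UGT2B11 and UGT2B15. These are paralogs whose probes can cross-hybridise. The list's median of -0.11 lay below the range of random lists (-0.096 to 0.16) and inside it after normexp background correction. Across the array 54 genes were at least 2-fold higher and 49 at least 2-fold lower of 13453 measured on both arrays. Another 89 and 62 genes had at-least folds past 2 because they were well above background on one of the arrays. In the brighter part of the array the counts were 2 and 16.

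In A3, genes known to respond to androgen were among those lower with bicalutamide. KLK3, which encodes prostate-specific antigen, was 8.05-fold lower with bicalutamide, HPGD, a prostaglandin-degrading enzyme, 3.94-fold lower and FKBP5 3.17-fold lower. The transcription factor ZBTB16 was 2.70-fold lower, KLK4 2.67-fold lower, SGK1 2.39-fold lower, KLK2 2.16-fold lower and the monoamine oxidase MAOA 2.07-fold lower. KLK2 and KLK3 are similar in sequence, and their separate values are uncertain. A further KLK2 probe had a log2 difference of 0.70, and the gene was under 2-fold with the mean over probes. KLK4, SGK1, KLK2 and MAOA were under 2-fold after normexp background correction. With KLK2, 8 of 28 measured androgen receptor targets were at least 2-fold lower and TARP was 2.09-fold higher, under 2-fold in 4 other settings. The list's median was -0.20, below 10000 random lists, and it was -0.090 over genes measured on all 4 arrays. Outside this list, the muscle gene MYOM2 was 14.3-fold lower, DDC, which makes dopamine and serotonin, 5.71-fold lower, the water channel AQP3 4.83-fold lower and NNMT 3.80-fold lower. AKR1C3, which reduces steroids and has close paralogs, was 2.81-fold lower. The probes of GREB1, a gene induced by estrogen and androgen receptors, disagreed, with log2 differences of -1.88 and 0.28.

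DNA replication genes were lower in A3 as well: 30 of 30 members had a negative difference, with a median of -0.47, below 10000 random lists. TYMS had a log2 difference of -0.77 and MCM10 -0.62. Mitotic genes had a median of -0.074, inside the central 95% of random lists (-0.10 to 0.094), with 19 of 26 members negative. After median scaling, which moved the median of all genes by -0.25, it was -0.32 against a range of -0.35 to -0.15. Interferon response genes had a median of 0.29 against a range of -0.091 to 0.13, and 20 of 24 members were positive. Estrogen receptor targets lay inside the range of random lists, with a median of 0.11 that was -0.14 after median scaling. In A3 616 genes were at least 2-fold higher and 59 at least 2-fold lower of 15511. This split depended on scaling, with 154 higher and 163 lower after quantile normalization and 155 and 120 after median scaling. More genes were higher than lower after normexp background correction (102 and 30), in the authors' value table (431 and 73) and in the brighter part of the array (109 and 17). The numbers were near each other at a 3-fold threshold (25 and 22) and with the brightness trend removed (185 and 179). The 616 higher genes were mostly dim, with a median log2 signal of -4.64 relative to the array's 75th percentile. Among the highest, DIO3, which inactivates thyroid hormone, was 7.37-fold higher and LGI4 5.46-fold higher. DIO3 was dim with DHT, at a signal of 10.6, and under 2-fold after normexp background correction. LGI4 was dim with DHT as well, at a signal of 36.7, so its fold size is uncertain.

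**Figure D1:**
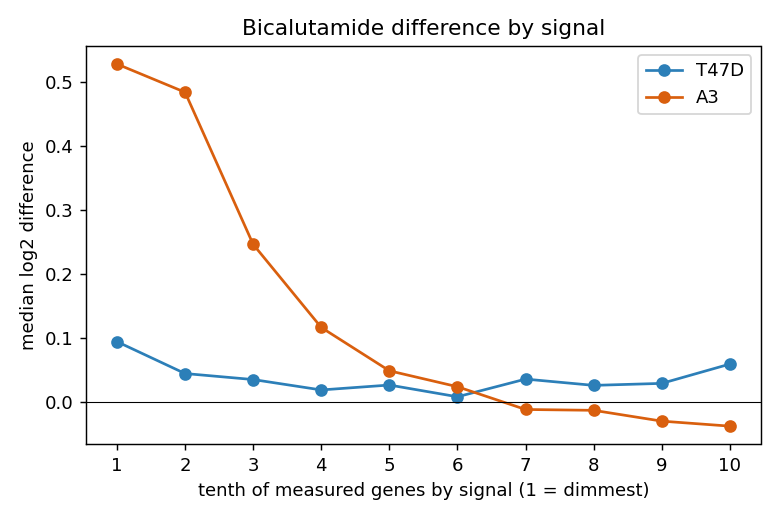
Median log2 difference (bicalutamide and DHT minus DHT alone) of measured genes, split by mean signal into 10 equal groups from the dimmest (1) to the brightest (10), for T47D and A3. In A3 the median was 0.53 in the dimmest group and -0.037 in the brightest, whereas in T47D it was 0.095 and 0.060.

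Genes that differed in the same direction in both lines are the closest this design has to a repeat, since the pairs of arrays share none. Lower in both were AQP3 (-1.63 in T47D and -2.27 in A3 on the log2 scale), the tight junction gene CLDN8 (-1.74 and -1.59), SGK1 (-2.22 and -1.26), UGT2B7, UGT2B10 and UGT2B11. C1orf116, named after its values were seen, had -2.59 and -1.21. Higher in both were CXCL12, NCMAP, RIPOR3 and the growth factor gene TGFB1, with CXCL12 at 1.14 and 1.54. Each lost 2-fold in a line under some setting: TGFB1 in A3 under 4, among them quantile normalization and median scaling, and in T47D under 2, NCMAP in A3 under 2, and RIPOR3 and CXCL12 in T47D under 1. SGK1 was under 2-fold in A3 after normexp background correction. These were 7 lower genes, where independent lists would share 0.126, and 4 higher genes against 1.41, and no gene was 2-fold apart in opposite directions. The counts cover genes measured on all 4 arrays, so genes with at-least folds were left out. MYOM2 was among those left out. Its signal in T47D was 102 with DHT and 12.4, not well above background, with bicalutamide, against 2321 and 160 in A3. The UGT2B genes are not independent of one another. After quantile normalization 2 were higher and 13 lower, and after median scaling 3 and 15, whereas with no detection filter 82 were higher and 22 lower. Across 13376 genes, which are not independent replicates, the differences of the lines had a Pearson correlation of 0.35, to which array position, shared by the treatment in both lines, can add.

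**Figure D2:**
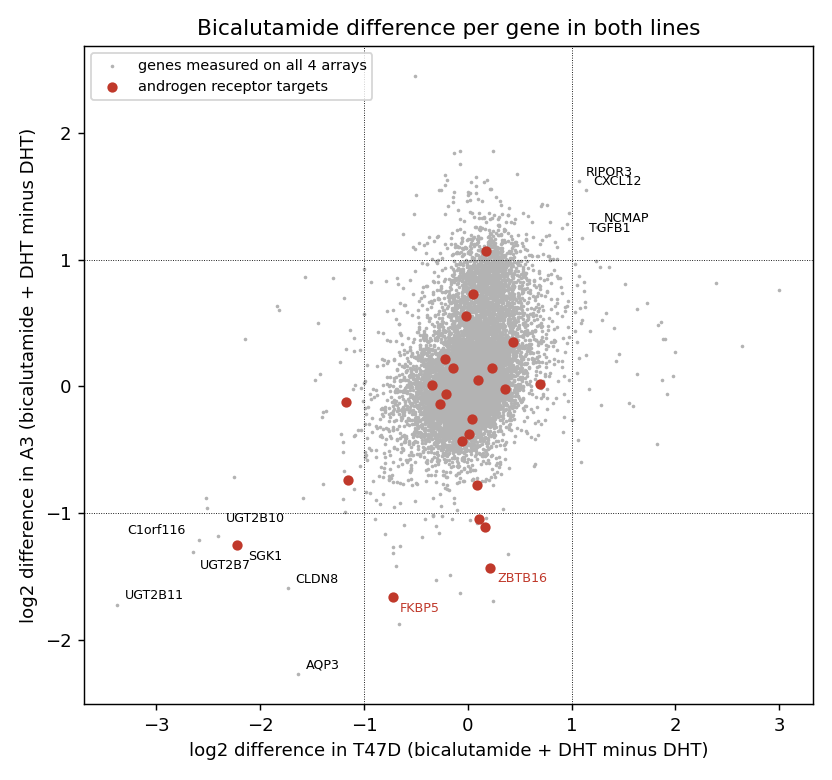
Log2 difference per gene (bicalutamide and DHT minus DHT alone) in T47D on the x axis and A3 on the y axis, for genes measured on all 4 arrays, with androgen receptor targets in red and dotted lines at 2-fold. The 7 genes 2-fold lower in both lines lie at the lower left and the 4 genes 2-fold higher in both at the upper right.

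The difference between the lines' bicalutamide differences was not tested. Mitotic genes had a median of 0.41 (A3 minus T47D), above 10000 random lists, and interferon response genes 0.38, also above them. Median scaling moved the median of all genes by -0.22 in this comparison, and these medians to 0.19 and 0.16. AURKB, for example, differed by -0.62 in T47D and -0.20 in A3. DNA replication genes had a median of 0.036 (-0.18 after median scaling), inside the range of random lists (-0.14 to 0.084), and androgen receptor targets -0.072, also inside it (-0.10 to 0.22). With no detection filter, androgen receptor targets lay outside the range, at -0.34. Among single genes, RBP5 and PGF, a placental growth factor gene, were lower with bicalutamide in T47D (-2.15 and -1.82) and not in A3 (0.37 and 0.60). Both were dim in A3 with DHT, at signals of 23.6 and 32.5, against 229 and 286 in T47D with DHT. The dimmest group of genes in A3 had a median difference of 0.53, so the contrast between the lines is uncertain for RBP5 and PGF. ZBTB16 had 0.22 in T47D and -1.43 in A3, and the cytochrome gene CYP4F8 0.25 and -1.70. In this comparison 259 genes were at least 2-fold higher and 49 lower, against 121 and 115 after quantile normalization and 113 and 111 after median scaling.

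The lines differed far more from each other than either did with bicalutamide, and genes of the estrogen receptor axis stood far lower in A3. ESR1, the estrogen receptor alpha gene, was 39.3-fold lower in A3 than in T47D with DHT and 39.6-fold lower with DHT and bicalutamide by its brightest probe. Its further measured probe had log2 differences of -1.04 and -0.15, so the size of the ESR1 difference is uncertain. The progesterone receptor gene PGR was not well above background in A3, which made it at least 403-fold lower with DHT and at least 461-fold lower with bicalutamide. Of 26 measured estrogen receptor targets 15 were at least 2-fold lower with DHT and 14 with bicalutamide, none was 2-fold higher, and the medians were -1.27 and -1.23, below 10000 random lists. GREB1 was 26.3-fold lower with DHT by its brightest probe, with a log2 difference of -4.71 against -1.69 for a further probe. SERPINA1 was 22.6-fold lower, IGFBP4 15.9-fold lower and the trefoil factor TFF3 10.3-fold lower. Luminal epithelial markers, a list that shares ESR1, GATA3, TFF3 and other members with further lists, had medians of -0.37 and -0.50, with the transcription factor GATA3 3.63-fold lower. Other genes low in A3 were SERPINA6, which encodes a corticosteroid-binding protein (381-fold lower), AGR3 (192-fold lower), SOX2 (54.6-fold lower), IGFBP5 (44.2-fold lower) and the receptor kinase ERBB4 (38.8-fold lower). AGR3, SOX2 and IGFBP4 were dim in A3 with DHT, at signals of 18.1, 11.3 and 31.5, so their fold sizes are uncertain. Growth factor signalling genes had a median of -0.59 with DHT, below the range of random lists (-0.51 to 0.18), and -0.33 with bicalutamide, inside it (-0.41 to 0.28) there and in 6 of 9 other settings.

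Androgen receptor targets stood higher in A3 on balance. KLK3 was 402-fold higher with DHT, ZBTB16 32.4-fold higher, AZGP1 8.40-fold higher, FKBP5 5.79-fold higher and KLK2 4.66-fold higher. With DHT in T47D, KLK3 was dim, at a signal of 38.6, so its fold size is uncertain. Of 26 measured androgen receptor targets 12 were at least 2-fold higher and 5 lower with DHT, with a median of 0.77, above 10000 random lists. With bicalutamide 10 of 24 were higher and 4 lower, with a median of 0.55, above the central 95% (-0.35 to 0.26). STEAP4 went the other way, at 6.06-fold lower with DHT, although a further probe had a log2 difference of -0.54. It was under 2-fold after normexp background correction. The broad androgen response list lay inside the range of random lists, with medians of 0.059 (-0.22 to 0.068) with DHT and -0.0024 (-0.18 to 0.11) with bicalutamide. With DHT 10 of its 91 measured members were at least 2-fold higher and 10 lower, and its median lay outside the range with no detection filter. Steroid-metabolising genes had a median of 0.14 with DHT, inside the range of random lists (-0.47 to 0.22), and inside it in 6 of 9 other settings, over which the median moved between -0.073 and 1.26. With bicalutamide the median was 0.58, above the range (-0.38 to 0.32), with 15 of 19 members positive. Among them, UGT2B11 was 23.3-fold higher with DHT, AKR1C3 12.9-fold higher and AKR1C1 7.49-fold higher, with cross-hybridisation between paralogs possible, and HSD17B2, which inactivates estradiol and testosterone, was 8.49-fold lower. HSD17B2 was dim in A3 with DHT, at a signal of 25.2, so its fold size is uncertain. Aromatase, CYP19A1, was not well above background on any of the 4 arrays. The genes that stood highest in A3 included APOD, a lipocalin (273-fold higher with DHT), HPSE2, a heparanase relative (103-fold higher), the nuclear receptor NR2F1 (61.4-fold higher), the adhesion gene FLRT3 (37.4-fold higher) and BMP7 (33.5-fold higher). APOD and NR2F1 were dim in T47D with DHT, at signals of 59.7 and 43.7, so their fold sizes are uncertain too. MUCL1, a breast mucin-like gene, was at least 245-fold higher.

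Cell cycle and interferon genes were also higher in A3. Mitotic genes had medians of 0.54 with DHT and 0.95 with bicalutamide, and DNA replication genes 0.69 and 0.65, each above 10000 random lists. CHAF1A, a chromatin assembly gene, was 2.24-fold higher and AURKB, a mitotic kinase, 2.12-fold higher with DHT. Interferon response genes had medians of 0.49 and 0.78, with 7 and 10 of 22 members at least 2-fold higher and none 2-fold lower, and IFI44 21.5-fold higher with DHT. The DHT value was inside the range of random lists in the brighter part of the array. Cholesterol synthesis genes had a median of 0.49 with DHT and p53 and apoptosis genes 0.58, with TP53I3 5.68-fold higher. Housekeeping genes had medians of 0.27 and 0.16, inside the range of random lists, with no member 2-fold apart, and -0.11 and -0.13 after quantile normalization. With DHT 757 genes were at least 2-fold higher and 1553 lower in A3 of 14063 measured, against 913 and 1182 after quantile normalization, 1051 and 1168 after median scaling and 979 and 1235 in the authors' value table. With bicalutamide 790 were higher and 1272 lower of 13438. Under both treatments 499 were higher and 987 lower, where independent lists would share 39.6 and 129.8. The 2 pairs share no array but share slides, so this repeat does not separate line from slide.

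**Figure D3:**
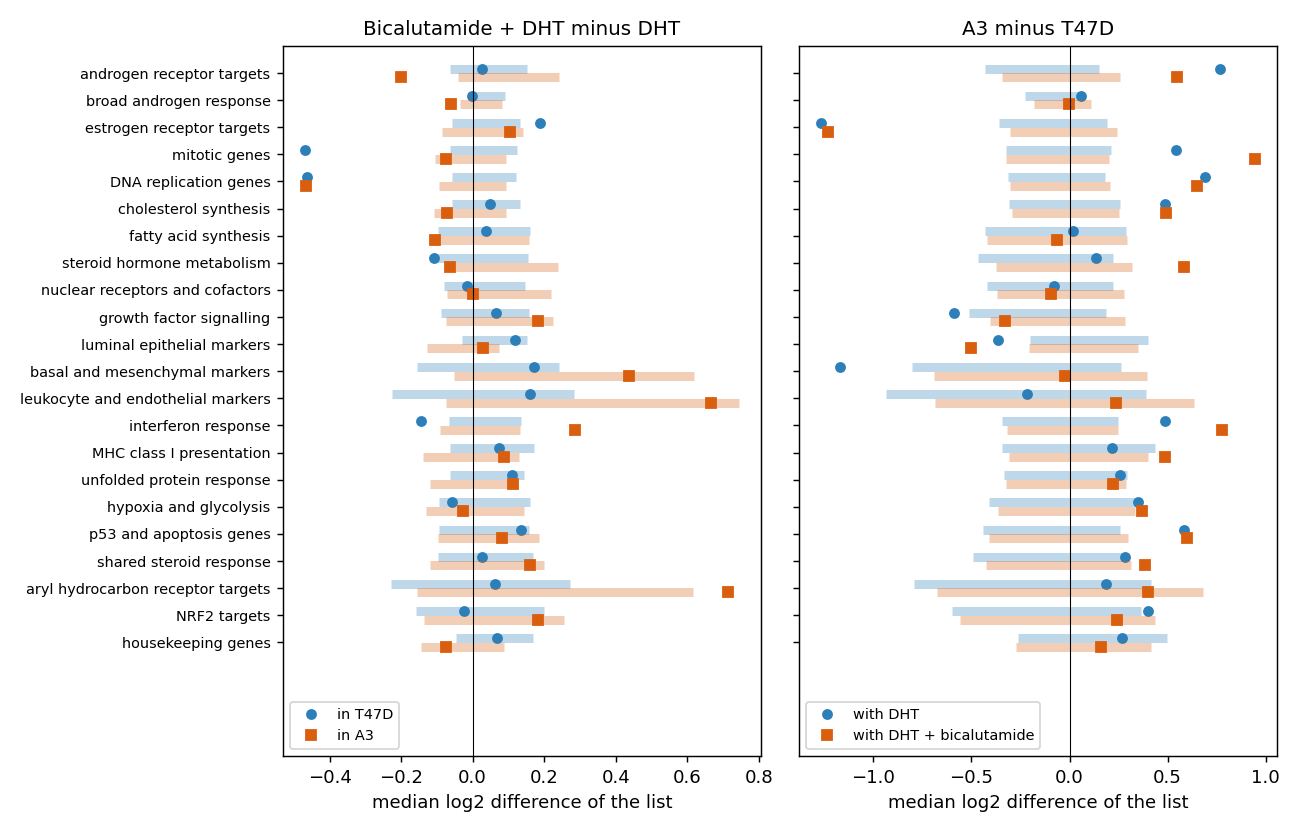
Median log2 difference of the 22 gene lists, for bicalutamide and DHT minus DHT alone in each line (left) and for A3 minus T47D under each treatment (right). Points are list medians and pale bars are the central 95% of 10000 random lists matched on brightness. DNA replication genes lie left of the bars in both lines, and estrogen receptor targets lie left of the bars between the lines under both treatments.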

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

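The tests on spike-in probes and on brighter and dimmer genes were chosen after the results were seen.

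Mitotic genes differed between the lines in their bicalutamide difference, with a median of 0.41 (A3 minus T47D). They stood out because 25 of 26 members were lower in T47D while the A3 median lay inside the range of random lists with 19 of 26 members lower, and the difference itself was not tested. The brightness-dependent shift between the A3 arrays is not the whole cause: after quantile normalization the median was 0.35, still above the central 95% of random lists. Nor did a few genes carry it, since 96.2% of the 26 measured members had a higher difference in A3. A line-specific response, a difference in growth state between the cultures and the single array per group stay open, as does an array position effect that differs between the slides.

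With bicalutamide more genes were at least 2-fold higher than lower in A3 (616 against 59). Over the genes brighter than the median on the A3 arrays, 97 were higher and 23 lower, and over the dimmer genes 519 and 36. A nonspecific rise of dim signal in the RNA or its labelling may contribute. The 130 olfactory receptor genes well above background on both A3 arrays, which breast cells are not known to use, had a median of 0.77. This lay above random lists of their brightness (0.29 to 0.54). Over all 365 olfactory receptor genes with no detection filter the excess was smaller, with a median of 0.47 against 0.37 to 0.39. The family was not dim throughout, since OR10H2 had signals of 633 and 1391 in A3. A scanner or hybridisation effect on every probe was not decided, since the 3 spike-in probes within the genes' brightness range lay at a median of -0.10 from genes of their brightness, with gaps from -0.22 to 0.010. Outside that range, a dimmer spike-in probe measured on both A3 arrays had a gap of -0.39, and brighter ones had gaps from -0.069 to 0.040. The skew among brighter genes was smaller and is left unexplained by dim signal, and a biological rise in A3 stays open and was not tested.

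Between A3 and T47D 499 genes were at least 2-fold higher and 987 lower under both treatments. A whole-array difference between the slides is not the whole cause, since the 7 spike-in probes well above background on all 4 arrays differed by at most 0.67 on the log2 scale. Each was higher on the A3 arrays, by 0.23 to 0.67 with DHT and 0.13 to 0.55 with bicalutamide, so an offset of that size stays open. The higher background of the T47D slide is not either, since 8.93% of the 8178 genes in the brighter part of the array were 2-fold apart in the same direction under both treatments, against 11.1% of the 13376 measured on all 4 arrays. Slide effects on single genes cannot be told apart from the line, because each slide holds one line.

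Interferon response genes stood out because their medians with bicalutamide lay on opposite sides of random lists, at -0.15 in T47D and 0.29 in A3, and this difference was not tested. After median scaling, which moved the median of all genes by -0.25 in A3, the A3 median was 0.039 against a range of -0.34 to -0.11. The difference between the lines, 0.38, lay above the range in each of the 9 other settings. Median scaling, the authors' value table and the filter on all 4 arrays could not have changed this rank. Fatty acid synthesis genes differed between the lines by a median of -0.32 (A3 minus T47D), also untested, which lay inside the range of random lists when probes were averaged. Among data outside the comparisons of genes, 6 probes with no gene symbol were at least 2-fold higher with bicalutamide in both lines and 0 lower, of 3583 measured.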

How the results depend on the processing

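Removal of the brightness trend was chosen after the data were seen, as were the androgen and estrogen receptor target lists as those with values given per setting; the other settings were planned. With slide as a block, the mean difference over both lines was at least 2-fold for 47 genes with bicalutamide (29 higher and 18 lower), against 11 past 2-fold in each line. In limma 0 of 13376 genes had an adjusted p under 0.05, the smallest was 0.362, and 1312 higher and 408 lower genes had an unadjusted p under 0.05; this fit has 1 residual degree of freedom and no further tool was run. Slide as a block was not run for the other counts: a comparison within a line lies on one slide, and between the lines slide is the line. Under these settings no difference of 2-fold or more of a named gene changed sign. Of 374 such differences 109 fell below 2-fold under at least 1 setting. Of 990 list medians under the alternatives 367 moved by more than the SD over spots and 23 by more than the SD between probes. The aryl hydrocarbon receptor targets for bicalutamide in A3 had a median of 0.71 over 7 genes, above random lists as in 4 of 9 other settings, and of -0.13 in the brighter part of the array. Among those 4 were median scaling and the authors' value table, which cannot change a list's rank. Median scaling moved the median of all genes by -0.25 for bicalutamide in A3, 0.15 between the lines with DHT and -0.22 for the difference of differences. Quantile normalization moved it by -0.10 and 0.11 for the first and second of these, and the authors' value table by 0.12 between the lines with DHT. Filters change how many genes are compared; for the other settings the cause was not tested. Signal over background limits the dim genes, more so on the T47D slide. After quantile normalization, the number of genes past the threshold was 317 for bicalutamide in A3. Androgen receptor targets then had medians of -0.34 for bicalutamide in A3, 0.87 for the lines with DHT and 0.47 for the lines with bicalutamide. Here estrogen receptor targets had medians of 0.011 for bicalutamide in A3, -1.16 for the lines with DHT and -0.12 for the difference of differences. After median scaling, the number of genes past the threshold was 275 for bicalutamide in A3 and 18 for bicalutamide in both lines. Androgen receptor targets then had medians of -0.45 for bicalutamide in A3, 0.92 for the lines with DHT, 0.48 for the lines with bicalutamide and -0.29 for the difference of differences. Here estrogen receptor targets had medians of -0.14 for bicalutamide in A3, -1.11 for the lines with DHT, -1.30 for the lines with bicalutamide and -0.25 for the difference of differences. After normexp background correction, the number of genes past the threshold was 40 for bicalutamide in T47D, 132 for bicalutamide in A3, 7 for bicalutamide in both lines, 1412 for the lines with DHT, 1368 for the lines with bicalutamide, 988 for the lines under both treatments and 89 for the difference of differences. Androgen receptor targets then had medians of 0.15 for bicalutamide in T47D, -0.12 for bicalutamide in A3 and 0.32 for the lines with bicalutamide. Here estrogen receptor targets had a median of -1.16 for the lines with DHT. With no detection filter, the number of genes past the threshold was 814 for bicalutamide in T47D, 1640 for bicalutamide in A3, 104 for bicalutamide in both lines, 5666 for the lines with DHT, 5578 for the lines with bicalutamide, 4201 for the lines under both treatments and 1976 for the difference of differences. Androgen receptor targets then had medians of 0.91 for the lines with bicalutamide and -0.34 for the difference of differences. Here estrogen receptor targets had a median of -1.49 for the lines with bicalutamide. Over genes well above background on all 4 arrays, the number of genes past the threshold was 398 for bicalutamide in A3. Androgen receptor targets then had medians of -0.090 for bicalutamide in A3 and 0.62 for the lines with DHT. In the brighter part of the array, the number of genes past the threshold was 18 for bicalutamide in T47D, 126 for bicalutamide in A3, 4 for bicalutamide in both lines, 992 for the lines with DHT, 1002 for the lines with bicalutamide, 730 for the lines under both treatments and 78 for the difference of differences. For estrogen receptor targets, the medians were -1.20 for the lines with DHT and -0.91 for the lines with bicalutamide. With the mean over probes, androgen receptor targets had a median of 1.01 for the lines with bicalutamide. Here estrogen receptor targets had medians of -1.33 for the lines with DHT and -1.01 for the lines with bicalutamide. In the authors' value table, androgen receptor targets had medians of -0.27 for bicalutamide in A3 and 0.89 for the lines with DHT. Estrogen receptor targets then had medians of 0.037 for bicalutamide in A3 and -1.14 for the lines with DHT. At a 3-fold threshold, the number of genes past the threshold was 30 for bicalutamide in T47D, 47 for bicalutamide in A3, 3 for bicalutamide in both lines, 890 for the lines with DHT, 732 for the lines with bicalutamide, 557 for the lines under both treatments and 45 for the difference of differences. With the brightness trend removed, the number of genes past the threshold was 364 for bicalutamide in A3. Androgen receptor targets then had medians of -0.31 for bicalutamide in A3, 0.88 for the lines with DHT and 0.48 for the lines with bicalutamide. Here estrogen receptor targets had medians of 0.030 for bicalutamide in A3 and -1.16 for the lines with DHT.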

Other observations

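The test of the hypothesis on genes lower in A3 was chosen after several of its genes had been seen.

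Other gene lists are given with the central 95% of random lists. Between the lines, hypoxia and glycolysis genes had medians of 0.35 (-0.41 to 0.33) with DHT and 0.37 (-0.37 to 0.34) with bicalutamide. Both lay inside the range in the brighter part of the array, and the bicalutamide value lay above it in 3 of 9 other settings. These were median scaling and the authors' value table, which cannot change a list's rank, and the filter on all 4 arrays. That filter kept 13376 of 13438 genes. VEGFA, an angiogenic factor, was 5.13-fold higher with DHT and the peptide hormone gene ADM 10.6-fold lower. NRF2 targets had 0.40 (-0.60 to 0.36) with DHT, which lay inside the range after normexp and in the brighter part of the array, and 0.24 (-0.56 to 0.44) with bicalutamide. The basal and mesenchymal markers had -1.17 (-0.80 to 0.26) over 9 genes with DHT, inside the range without a detection filter, after normexp and in the brighter part of the array. With bicalutamide they had -0.022 (-0.69 to 0.39) over 8 genes. MHC class I genes had 0.21 (-0.34 to 0.44) with DHT and 0.49 (-0.31 to 0.40) with bicalutamide, the latter inside the range with the mean over probes. Leukocyte and endothelial markers lay inside it, at -0.22 (-0.94 to 0.39) and 0.24 (-0.69 to 0.64).

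With bicalutamide in A3, the broad androgen response list had a median of -0.059, below the central 95% of random lists (-0.034 to 0.082) under each of the 9 other settings with list values as well. It shares members with the androgen receptor targets and is not independent of them. Its 5 members at least 2-fold lower (KLK3, HPGD, FKBP5, SGK1 and KLK2) are in both lists, and 2 members were at least 2-fold higher. In T47D the broad list had -0.00067 (-0.014 to 0.091), inside the range there and in 7 of 9 other settings. Unfolded protein response genes had 0.11 in A3, above the range (-0.12 to 0.10) in those settings too, although the median was -0.14 after median scaling, which lowered the genes together. In T47D they had 0.11 (-0.064 to 0.14). The steroid response list shared with other receptors had 0.025 (-0.097 to 0.17) in T47D and 0.16 (-0.12 to 0.20) in A3, and -0.025 and -0.072 after quantile normalization. Nuclear receptors and cofactors had -0.015 (-0.079 to 0.15) and 0.00022 (-0.073 to 0.22), with -0.25 in A3 after median scaling.

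The hypothesis was that genes lower with the antagonist in A3 may belong to those that A3 uses more than T47D. Their difference between the lines was taken under bicalutamide, where noise of the shared array would pull it down. Of the 59 genes at least 2-fold lower, 35 were measured on both bicalutamide arrays, and their median difference was 0.90, above the central 95% of random lists of their brightness (-0.28 to 0.24). Of these 16 were at least 2-fold higher and 8 at least 2-fold lower in A3. Over all 13438 genes measured on these arrays 790 were at least 2-fold higher and 1272 lower. Both directions were thus more frequent in the list. The values go with the hypothesis, but also with a list rich in genes that differ between the lines either way. Slide differences between the lines leave the hypothesis open.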
